A study of Danio rerio with 16 samples.

How the data were processed

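The series holds bulk RNA-seq of sorted zebrafish brain cells, with 16 libraries in 4 groups of 4. Per the labels' protocols, brains were taken from transgenic fish aged 1 month, 8 brains were pooled per replicate, the tissue was dissociated with papain, and fluorescent cells were separated by flow cytometry. In one line the enhancer-trap driver 76A expressed the calcium indicator GCaMP6s in the lateral hypothalamus, and in the other the driver 116A expressed GFP in the caudal hypothalamus. The labels call the GCaMP6s-positive cells LH and the GCaMP6s-negative cells non-LH, and the GFP-positive cells cH and the GFP-negative cells non-cH. RNA was amplified with a SMART-seq protocol for low input and tagmented with Nextera XT, per the labels' protocols. The submitters' processing notes name FastQC, STAR and the genome build GRCz11, without versions. No label states the read counter, its treatment of reads that map to several places, or a use of strand, and the amplification does not mark strand.

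The authors deposited 1 table of raw read counts per gene, whole numbers without normalisation. It has 47038 rows, of which 9 were left out because they held fragments of coordinate strings in place of a gene name or count; the remaining 47029 rows were used, and 16135 of them were at 0 in every library. The 16 columns were matched to the samples by their names. Of the rows, 9649 are transfer RNA genes. A further 12757 rows share a symbol with another row, written with the endings _1, _2 and so on, for 5880 symbols; 39.8% of these rows were at 0 in every library, against 10.7% of the other rows that are not transfer RNA genes. The files do not say what the copies are, and reads of near-identical copies can be split between them or lost, so values of such rows are uncertain. They were tested as deposited, with a sum per symbol as an alternative.

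Total counts ran from 26.8 M to 49.4 M per library. Libraries were scaled with TMM factors and values are given as CPM of the scaled library, as mean ± SD over the 4 libraries of a group. Where all libraries of a group were at 0, folds are lower bounds against a floor of 3 counts over the group; with 1 to 3 counts in a group the ratio of counts is given with its exact 95% binomial interval. PCR reads without molecular identifiers are not independent molecules, so floors and intervals cover at most counting error. Many low counts were even, as for adnpb_1 in the cH libraries (6, 8, 0 and 4). If both reads of a pair were counted, which no label states, the intervals are too narrow and the lower bounds of folds too high.

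Differential expression was tested with edgeR 4.0.16 under R 4.3.3: filterByExpr with its defaults (a minimum count of 10 and a minimum total count of 15) kept 22318 genes, and the quasi-likelihood F test with robust estimation was run on 1 model of all 16 libraries with 4 group means, two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. All groups share 1 estimate of the spread in this model. Standard errors (SE) of log2 fold changes are the log2 fold change divided by the square root of F. The contrasts were LH against non-LH, cH against non-cH, LH against cH, non-LH against non-cH, and the difference of the first pair of contrasts. Single genes were also compared with exact permutation tests of the CPM, two-sided.

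The 25 gene lists and the rule for named genes were fixed before the data were examined. The lists hold 555 symbols, of which 538 were found in the table, 13 of them through a synonym in a RefSeq table of assembly GRCz12tu, from which no coordinates were taken. They were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and again with an estimated correlation, with adjustment over the 25 lists. The lists cover serotonergic, catecholaminergic and histaminergic, GABAergic, glutamatergic, feeding neuropeptide, growth hormone and tachykinin axis, feeding receptor and hypothalamic transcription factor genes (8 main lists). The others cover telencephalic, midbrain and hindbrain, pan-neuronal, radial glia, oligodendrocyte, microglia, endothelial, erythrocyte, lymphoid, meningeal, ependymal, pituitary and photoreceptor markers, immediate early, heat shock, ribosomal protein and mitochondrial genes. For the comparisons of positive cells the rule took the 8 most raised and 4 most lowered genes past the threshold whose groups did not overlap, with a mean of at least 10 CPM in the higher group and an established symbol. The comparison of negative cells and the difference of differences gave 3 genes each way. To these it added, in LH against non-LH and cH against non-cH, the 2 members with the smallest p of each main list, and of each other list that passed camera or had at least 5 calls, and a fixed set of genes whatever their result. For 1 gene that the rule names in the comparison of negative cells the result is not reported here.

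In simulated data with 50 genes changed at each size, edgeR recovered for LH against non-LH 0% of genes changed 2-fold, 22% at 4-fold, 40% at 8-fold and 50% at 16-fold, with 0 false calls among 56 over 21604 genes. For cH against non-cH the shares were 0%, 22%, 30% and 54%, with 1 false call among 54 over 21553 genes. DESeq2 1.42.0 made 165 false calls of 267 in the first and 174 of 278 in the second simulation, and limma-voom 1 of 41 and 3 of 53. Every simulated group had the same spread per gene, estimated over all 16 libraries. The shares therefore do not show recovery at the spread of a single line. In the real LH against non-LH fit 295 of 335 calls were at least 2-fold, so some smaller changes were called.

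The alternatives fixed beforehand were RLE and upper-quartile scaling, DESeq2, limma-voom with quality weights, no filter and a stricter filter (10 counts in 8 libraries), each library left out, only the 8 libraries compared, a replicate block, no robust estimation, and a 2-fold minimum. After the data were seen, rows of a symbol were summed, cH libraries 1 and 2 were set aside, and all 4 cH libraries were set aside. Python 3.11.15 with matplotlib 3.10.9 drew the plots.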

Results

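Reporter-positive and reporter-negative brain cells sorted from 2 hypothalamic driver lines gave 16 libraries, 4 each of LH, non-LH, cH and non-cH, each from 8 pooled brains. Totals averaged 36.1 ± 2.73 M counts in LH, 41.1 ± 3.44 in non-LH, 36.5 ± 9.69 in cH and 42.2 ± 3.46 in non-cH (SD, n = 4). The cH libraries stood apart: they detected 16816 ± 2160 genes, against 22021 ± 374 in LH, 23231 ± 208 in non-LH and 22295 ± 888 in non-cH. Their 10 most abundant genes took 19.4% ± 3.54 of the counts, against 9.46% ± 1.17 in LH. Correlations of log2 CPM across genes had a median of 0.654 between cH libraries (range 0.614 to 0.79), and of 0.862 between LH, 0.89 between non-LH and 0.845 between non-cH libraries. cH libraries 1 and 2 detected 14847 and 15049 genes, and libraries 3 and 4 detected 18588 and 18779.

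**Figure D1:**
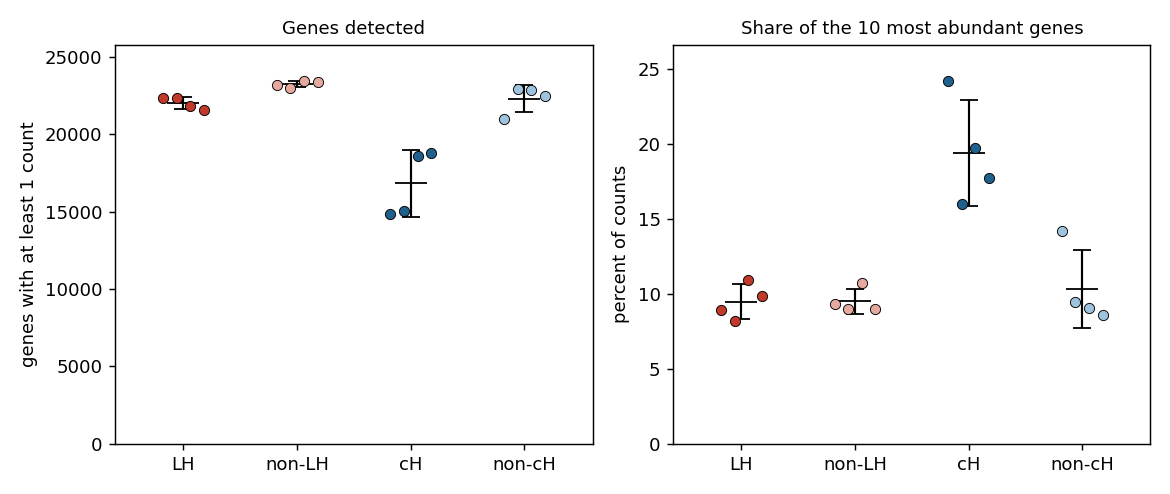
Genes with at least 1 count (left) and the percent of counts in the 10 most abundant genes (right), 1 point per library, with the mean and SD of 4 libraries per group as bars. The cH libraries lie lowest in genes detected, between 14847 and 18779.

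LH cells were compared with non-LH cells to find what marks the lateral hypothalamic population among brain cells; the series title ties the question to growth hormone and tachykinin signalling in feeding. Of 22318 genes tested, 138 were higher and 197 were lower in LH. Among the genes named for the largest rises, add3b, which encodes an adducin of the membrane skeleton, was at 77.9 ± 23.3 CPM in LH and 2.14 ± 1.51 in non-LH (SD, n = 4; log2 fold change 5.18 ± 0.64 SE, adjusted p = 0.000685). Another row of that symbol, add3b_1, chosen after its values were seen, rose by 3.1 in LH and by 1.93 in cH, each against its negative cells. The protein kinase C gene prkcbb was at 1590 ± 119 and 114 ± 18.3 CPM (3.8 ± 0.54, adjusted p = 0.0021). The onecut transcription factor gene onecutl was at 501 ± 97.1 and 39.3 ± 7.41 CPM (3.67 ± 0.37, adjusted p = 0.000126). Also higher were kctd4_1 (log2 fold change 4.31) and nrgna (3.77), which encodes the calmodulin-binding protein neurogranin. The same held for ryr3 (3.65), a ryanodine receptor gene, and map6d1 (3.55). The row ces2_1, a carboxylesterase gene with a second row, was at 11.2 ± 5.21 CPM in LH and at 0 in all 4 non-LH libraries, at least 645-fold higher. Of the 4 genes named for the largest falls, the globin genes ba1l, ba1 and hbaa1 had log2 fold changes of -5.10, -5.03 and -4.99, and epb41b, a membrane skeleton gene, -3.92.

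The count of genes changed with the libraries in the fit. With a block on the sample number, given with the dependence on the processing, 80 genes passed, 77 of them among the 335. With only the 8 LH and non-LH libraries in the fit, 2548 genes passed, 1378 of them higher, and they included 330 of the 335. With the 4 cH libraries set aside, an alternative added after the data were seen, 2356 passed. Leaving out any single LH or non-LH library gave 141 (without non-LH replicate 4) to 196 genes (without LH replicate 3), while 580 passed without cH replicate 1 and 599 without cH replicate 2. Of the 24 named calls in this comparison, 12 ended when some single library was left out. They were those of ces2_1, kctd4_1, nrgna, ryr3, ba1l, ba1, epb41b, th2, slc6a1a, slc17a6a, her4.2 and egr4. They had highest adjusted p from 0.0642 (egr4, without non-LH replicate 1) to 0.174 (slc6a1a, without non-LH replicate 3). Those 12 all passed in the fit of 8 libraries.

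**Figure D2:**
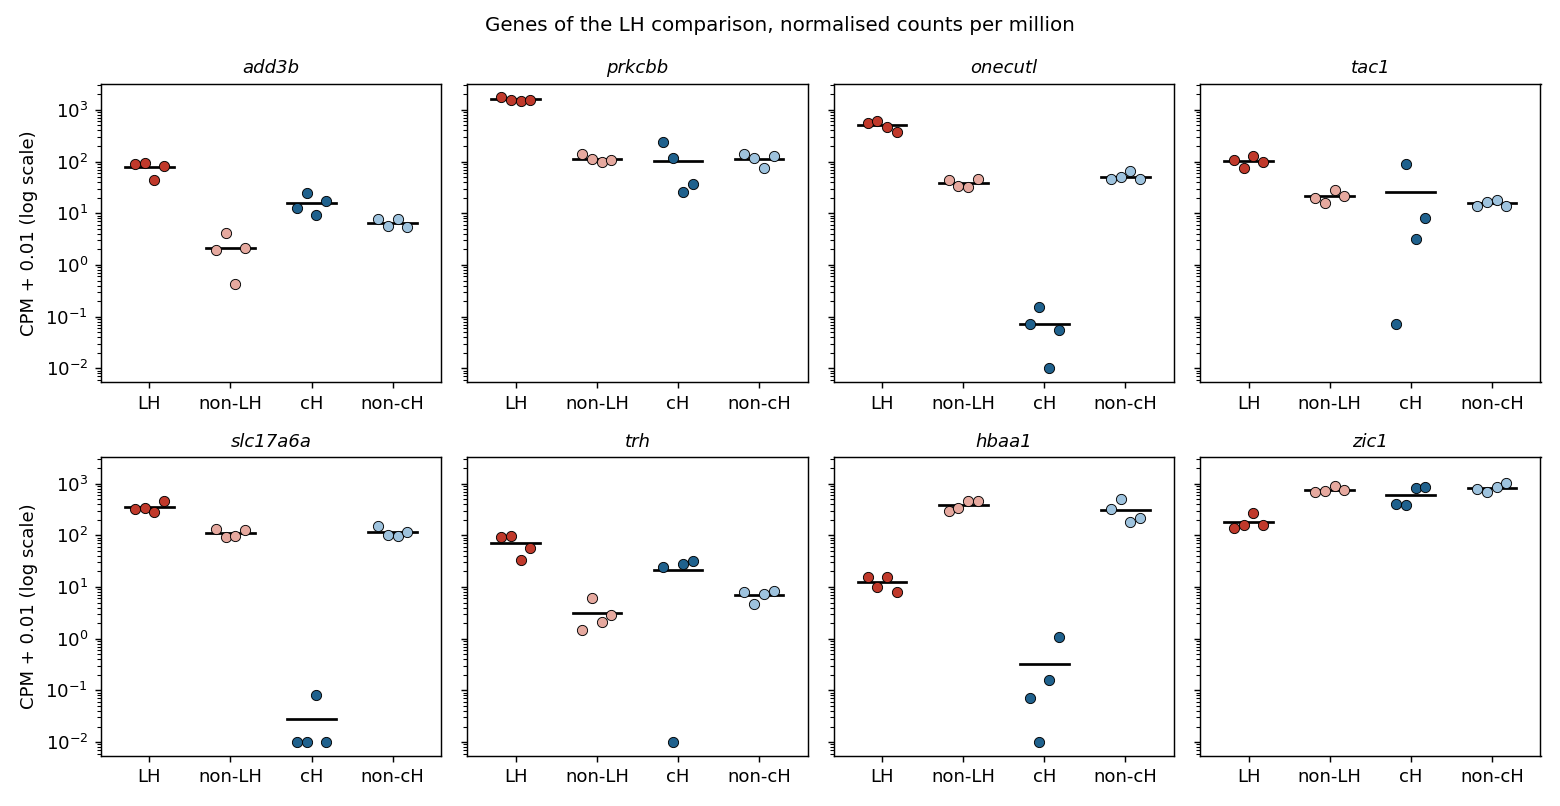
CPM plus 0.01 on a log axis for 8 genes named in the LH comparison, 1 point per library and a line at the mean of 4. The LH points of tac1 and slc17a6a lie above all non-LH points, and those of hbaa1 and zic1 lie below them.

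Tachykinin, growth hormone and feeding peptide genes had the following levels in LH cells. The tachykinin precursor gene tac1 was at 101 ± 20.8 CPM in LH and 21.3 ± 5.25 in non-LH, with no overlap (SD, n = 4; exact permutation p = 0.0286, the smallest that 4 against 4 allow). Its log2 fold change of 2.25 ± 1.11 had an adjusted p of 0.571 in the 16-library fit, where cH libraries ranged widely in tac1, and of 0.000195 (2.24 ± 0.22) in the fit of 8 libraries. Growth hormone itself, gh1, had 0 counts in all 16 libraries. In the growth hormone and tachykinin list 0 of 27 tested members passed over all genes, and 0 when adjusted over the list alone. Camera placed the list higher (adjusted p = 0.00274, and adjusted p = 0.0397 with an estimated correlation). In the 8-library fit 4 members passed, all higher: tac1, ghrhrb_1, sstr1a and igfbp5b, the last 2 chosen after their values were seen. There ghrhrb_1, a row of a growth hormone releasing hormone receptor gene, was at 3.73 ± 0.89 (adjusted p = 0.0227). In the 16-library fit its adjusted p was 0.326, and its change ran from 3.35 to 4.82 with 1 library left out. In the 8-library fit sstr1a, a somatostatin receptor gene, was at 2.13 ± 0.25 and igfbp5b at 0.72 ± 0.20. Of 38 feeding neuropeptide genes 0 passed over all genes and 0 adjusted over the list alone (camera adjusted p = 0.396). In the 8-library fit 9 were higher and 4 lower. Among them were trh, the thyrotropin-releasing hormone gene, at 69.7 ± 30.6 and 3.18 ± 2.13 CPM (adjusted p = 0.0901 in the 16-library and 0.000595 in the 8-library fit), and penkb, a proenkephalin gene, at 38.3 ± 6.34 and 11.5 ± 1.29 CPM (0.121 and 0.000497). The granin genes vgf (2.23 ± 0.14) and scg2b (1.61 ± 0.11) were also higher there, and were named after their values were seen. Neither hcrt, the hypocretin gene, with 42 counts in LH and 38 in non-LH, nor agrp, with 0 and 12 counts, marked LH cells. pmch had 2 counts in LH against 2169 in non-LH, a 952-fold lower share (95% counting interval 263 to 7870, adjusted p = 0.199). npy was at 8.99 ± 4.59 and 20.5 ± 5.94 CPM (adjusted p = 0.755), and pomca at 0.564 ± 0.478 and 4.71 ± 1.66 (adjusted p = 0.733, and 0.0389 in the 8-library fit). The exact permutation p was 0.0286 with no overlap for trh and pomca, 0.0571 for npy, 0.143 for pmch and 1 for hcrt and agrp.

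Of the fast transmitter lists in LH cells each had 1 call. The vesicular glutamate transporter gene slc17a6a was at 350 ± 74.9 CPM in LH and 113 ± 20.9 in non-LH (log2 fold change 1.64 ± 0.38, adjusted p = 0.0442), the only call among 5 glutamatergic genes (camera adjusted p = 0.955, with a negative median and an upward test), also when adjusted over the list alone. Of 10 GABAergic genes slc6a1a, a GABA transporter gene, was higher (0.73 ± 0.17, adjusted p = 0.0467; 1 call over the list alone; camera adjusted p = 0.668), and gad1b was at 156 ± 51.1 and 106 ± 20.5 CPM (adjusted p = 1). slc17a6b was at 55.9 ± 8.14 and 73.4 ± 5.31 CPM (adjusted p = 1). th2, a tyrosine hydroxylase gene, fell to 0.134 ± 0.20 CPM from 6.51 ± 2.61 in non-LH (log2 fold change -5.61, and -7.37 without LH replicate 3; adjusted p = 0.0307), 1 of 7 catecholaminergic and histaminergic genes to pass and 2 when adjusted over the list alone. Camera placed the catecholaminergic list lower (adjusted p = 0.00221, and adjusted p = 0.0397 with an estimated correlation). Of 15 serotonergic genes 0 passed on either adjustment, and the camera call (adjusted p = 0.0384) was lost, adjusted p = 0.10 with an estimated correlation. tph1b was at 0 in LH and 1.62 ± 1.1 CPM in non-LH, at least 78.7-fold lower (adjusted p = 0.293, and 0.0101 in the 8-library fit). It was the 1 call there among 14 serotonergic genes. tph1a was at 2.48 ± 1.57 and 2.94 ± 1.41 CPM. The exact permutation p was 0.0286 with no overlap for th2, slc17a6a and slc17a6b, 0.0571 for gad1b and tph2_1, 0.143 for slc6a4a, 0.629 for tph1a and 0.714 for slc6a4b. Of 29 receptor genes for feeding signals 0 passed on either adjustment (camera adjusted p = 0.163), and in the 8-library fit 4 were higher and 1 lower.

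Lists of regional and other cell type markers were tested in LH cells; of the genes named here lef1, rx3, en1b, zic4, id1 and mki67 were chosen after their values were seen. Of 41 hypothalamic transcription factor genes 3 were lower, also over the list alone: foxb1a (log2 fold change -2.15 ± 0.30), lef1 and fezf2, the last at 0 in LH and at least 183-fold lower (camera adjusted p = 0.000161, and adjusted p = 0.0397 with an estimated correlation). In the 8-library fit 15 were lower and 3 higher, rx3 among the latter (2.39 ± 0.46). Midbrain and hindbrain markers en1b, en2b, zic1 and zic4 fell by 2.05, 2.22, 2.08 and 2.23 on the log2 scale, 4 of 19 tested (4 lower and 1 higher over the list alone; camera adjusted p = 1.63e-07, and adjusted p = 0.0397 with an estimated correlation). Telencephalic markers had 0 of 13 past the threshold and 1 lower over the list alone. Their camera call (adjusted p = 0.00509) was lost at adjusted p = 0.0526 with an estimated correlation, and 6 were lower in the 8-library fit. Of 18 radial glia and progenitor genes her4.2, id1, mki67 and pcna were lower. Over the list alone 10 were lower and 1 higher (camera adjusted p = 3.34e-06, and adjusted p = 0.0397 with an estimated correlation). Cytosolic ribosomal protein genes took 0.722% ± 0.081 of counts in LH and 1.5% ± 0.132 in non-LH. Of 76 tested 21 were lower, and 67 over the list alone, with rpsa at -1.1 ± 0.17 and rplp0 at -1.28 ± 0.23 (camera adjusted p = 1.65e-45, and adjusted p = 0.0397 with an estimated correlation). Erythrocyte genes took 0.00544% of counts in LH and 0.171% in non-LH, with 3 of 7 lower and 7 over the list alone (camera adjusted p = 3.66e-16, and adjusted p = 3.91e-05 with an estimated correlation). Endothelial genes were placed lower by camera (adjusted p = 0.00274, and adjusted p = 0.0397 with an estimated correlation) with 0 of 16 past the threshold and 1 lower over the list alone. In the 8-library fit 1 of 15 was higher and 0 were lower. Among 20 immediate early genes egr4 rose (1.06 ± 0.20, adjusted p = 0.0152; 2 over the list alone; 8 higher in the 8-library fit). fosab was at 2590 ± 311 and 2030 ± 115 CPM with no overlap (adjusted p = 0.989, and 0.0285 in the 8-library fit, with an exact permutation p = 0.0286). The camera calls for immediate early genes (higher), microglia (higher), oligodendrocyte (lower) and meningeal genes (lower) were lost, at adjusted p = 0.455, 0.427, 0.427 and 0.155 with an estimated correlation. These 3 cell type lists had 0 of 14 microglia, 0 of 14 oligodendrocyte and 0 of 8 meningeal genes past the threshold, and 0, 0 and 2 lower over the list alone. No camera call was made for pan-neuronal genes (1 lower of 19, and 2 higher and 1 lower over the list alone). The same held for lymphoid (0 of 4), ependymal (0 of 8), pituitary (0 of 2), photoreceptor (0 of 14), heat shock (0 of 17) and mitochondrial genes (0 of 2), where 0 passed over the list alone as well. In the 8-library fit 4 pan-neuronal genes were higher and 5 lower. Higher there were also 3 of 13 microglia and 2 of 17 heat shock genes, with 0 lower in either. Lower were 1 pituitary, 1 photoreceptor and 1 mitochondrial gene, and 0 oligodendrocyte, meningeal, lymphoid or ependymal genes passed.

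cH cells were compared with non-cH cells to find what marks the caudal hypothalamic population, and 1542 genes were higher and 2874 lower of 22318. That is more than in LH in the 16-library fit, but the order turned in the fits of 8 libraries, with 2157 genes for cH and 2548 for LH. tph1a, th2 and most radial glia genes were higher and most pan-neuronal genes lower. tph1a, the tryptophan hydroxylase gene of serotonin synthesis, was at 172 ± 180 CPM in cH and 3.93 ± 1.95 in non-cH (SD, n = 4; log2 fold change 5.45 ± 0.94, adjusted p = 0.000711). th2 was at 218 ± 249 and 5.76 ± 6.04 CPM (5.24 ± 1.14, adjusted p = 0.00421). mao, monoamine oxidase, and gch1, of tetrahydrobiopterin synthesis, rose by 2.83 ± 0.36 and 3.53 ± 0.59. In all 3 of 15 serotonergic genes were higher, and 4 over the list alone. The list's camera call (adjusted p = 0.00935) was lost at adjusted p = 0.0672 with an estimated correlation. slc6a4b, a serotonin transporter gene, was at 15.7 ± 9.78 and 0.332 ± 0.664 CPM with no overlap (adjusted p = 0.162; exact permutation p = 0.0286). tph2_1, slc6a4a and pomca had adjusted p of 0.563, 0.628 and 0.387 (exact permutation p = 0.257, 0.286 and 0.286). With cH libraries 1 and 2 set aside, an alternative added after the data were seen, 4 serotonergic genes were higher and 1 lower of 16, with a median log2 fold change of 0.761 against 2.23. Of 7 catecholaminergic genes th2 was higher and th, at 0 in cH and 0.672 ± 0.536 CPM in non-cH, was at least 29.6-fold lower (2 higher and 2 lower over the list alone; camera adjusted p = 0.755, with a negative median and an upward test).

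The 8 genes named for the largest rises in cH were mostly near 0 in non-cH. kif13bb, tspan12 and lrguk were at 19.7 ± 35.0, 14.5 ± 9.26 and 12.3 ± 10.7 CPM in cH and at 0 in non-cH, at least 1140-fold, 839-fold and 716-fold higher. The value of kif13bb rests on cH replicate 1 at 72.2 CPM, with the other cH libraries at 3.68, 0.73 and 2.23: without it the rise was at least 128-fold, and without cH replicate 2 that of lrguk was at least 451-fold. tgm1l3, a transglutaminase gene, had 2513 counts in cH and 2 in non-cH, a ratio of 1450 (95% counting interval 402 to 12000). efcab6 was at 19.0 ± 15.4 and 0.049 ± 0.098 CPM, the islet-family row isl1l at 48.4 ± 30.2 and 0.359 ± 0.719, and myo18aa at 725 ± 281 and 6.46 ± 5.49 (log2 fold change 6.81 ± 1.16, adjusted p = 0.000672); tagln2_1 was at 36.7 ± 28.9 and 0.338 ± 0.591. In the other direction scrt1a, eomesb, golga7bb and mrc1a had 0 counts in all 4 cH libraries and 113 ± 19.3, 101 ± 33.7, 88.2 ± 18.2 and 72.8 ± 26.2 CPM in non-cH, at least 4980-fold, 4440-fold, 3890-fold and 3210-fold lower.

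**Figure D3:**
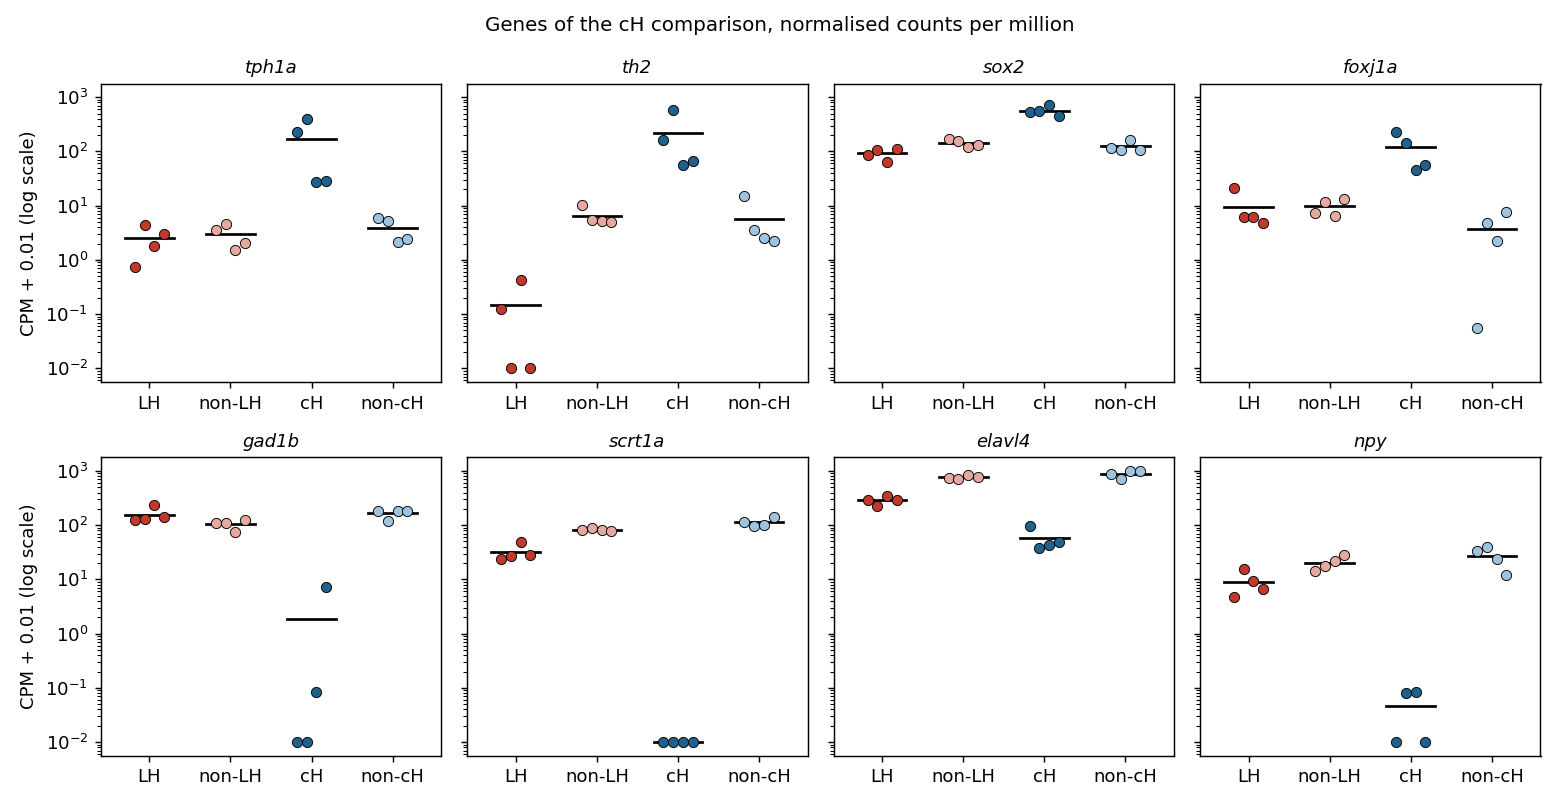
CPM plus 0.01 on a log axis for 8 genes named in the cH comparison, 1 point per library and a line at the mean of 4; points at the bottom are libraries at 0. The cH points of tph1a and th2 lie above all non-cH points, and scrt1a is at 0 in all 4 cH libraries.

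The radial glia and progenitor list took 8.23% ± 1.73 of counts in cH (6.11% to 9.92%) and 0.735% ± 0.346 in non-cH. It had 11 of 18 members higher and 1 lower (11 and 2 over the list alone; camera adjusted p = 2.79e-13, and adjusted p = 0.00549 with an estimated correlation). id1 and sox2 rose by 2.57 ± 0.23 and 2.18 ± 0.22. The glial glutamate transporter gene slc1a2b, the connexin gene cx43 and the glutamine synthetase gene glula, rose by 4.22 ± 0.51, 4.19 ± 0.67 and 3.62 ± 0.43, and the proliferation marker mki67 fell by 2.55; these 4 were named after their values were seen. Ependymal genes foxj1a (5.01 ± 1.05), foxj1b (5.03 ± 1.21, chosen after its value was seen) and rfx2 (2.23 ± 0.36) were higher, 3 of 8 tested and 4 over the list alone, with a camera call (adjusted p = 0.00132) lost at adjusted p = 0.173 with an estimated correlation. foxj1a was at 228 and 143 CPM in cH libraries 1 and 2 and at 45.7 and 56.7 in 3 and 4; with the first 2 set aside 2 ependymal genes were higher, and the list's median log2 fold change was 1.36 against 3.34. Pan-neuronal markers took 0.0986% ± 0.0677 of counts in cH and 1.02% ± 0.10 in non-cH. Of these 15 of 19 were lower, 17 over the list alone (camera adjusted p = 9.1e-16, and adjusted p = 0.00549 with an estimated correlation); elavl4 fell by 3.97 and stmn2a by 4.39.

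**Figure D4:**
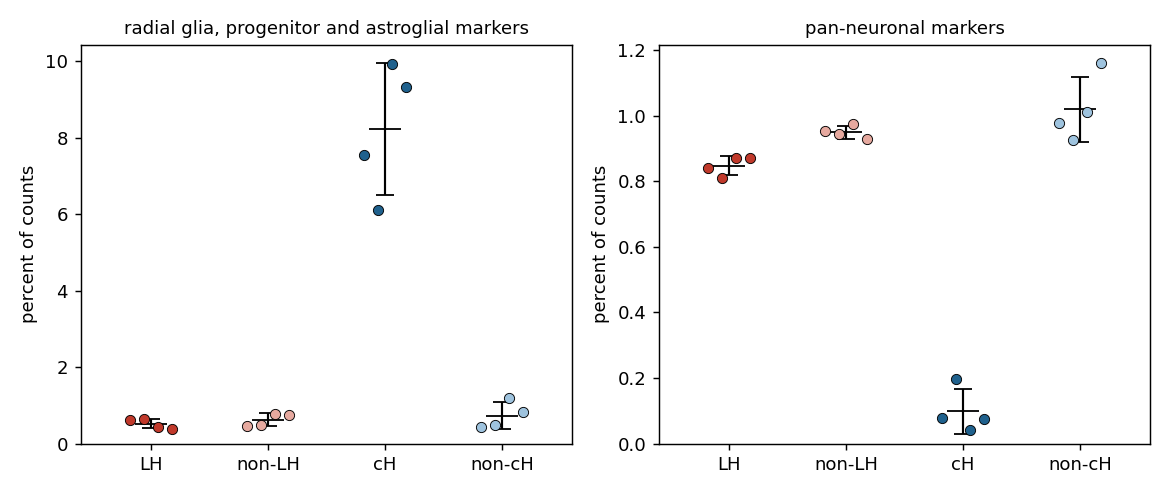
Percent of counts taken by the radial glia list (left) and the pan-neuronal list (right), 1 point per library, with the mean and SD of 4 libraries per group as bars. The cH libraries lie between 6.11% and 9.92% for the first list, and the highest other library is at 1.19%.

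The glutamatergic and feeding neuropeptide lists were lower in cH, and the GABAergic list had no camera call. slc17a6a had 2 counts in cH against 20038 in non-cH, an 8660-fold lower share (95% counting interval 2400 to 71500), the 1 call among 5 glutamatergic genes on either adjustment (camera adjusted p = 0.000274, and adjusted p = 0.00839 with an estimated correlation). gad1b was at 1.86 ± 3.68 and 167 ± 32.1 CPM (log2 fold change -6.46 ± 1.45), and the GABA transporter gene slc6a1b was higher (2.47 ± 0.35) and slc6a1a lower, 3 calls among 10 GABAergic genes on either adjustment (camera adjusted p = 0.894). Of 38 feeding neuropeptide genes 12 were lower, and over the list alone 16 were lower and 1 higher (camera adjusted p = 0.000274, and adjusted p = 0.0433 with an estimated correlation). uts1, a urotensin gene, was at 0 in cH and at least 1570-fold lower, and npy was at 0.0359 ± 0.0415 against 27.2 ± 12.2 CPM. hcrt and pmch had 0 counts in cH and 77 and 323 in non-cH, and agrp and gh1 had 0 in both. tac1 was at 25.7 ± 44.0 and 15.6 ± 1.86 CPM (0.73 ± 1.07, adjusted p = 0.709; exact permutation p = 1), a difference whose sign turned without cH replicate 2, at -2.03. Of 27 growth hormone and tachykinin genes igf2b_1 was higher and 4 were lower, tacr3l at least 197-fold (camera adjusted p = 0.894), the same numbers over the list alone. Of 29 feeding receptor genes 1 was higher and 4 lower on either adjustment, npy8ar and drd3 at 0 in cH and at least 174-fold and 165-fold lower (camera adjusted p = 0.50).

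Of 41 hypothalamic transcription factor genes 3 were higher in cH, nkx2.4a (2.00 ± 0.40), nkx2.4b (1.76 ± 0.43), both chosen after their values were seen, and isl1l, and 12 lower, 14 over the list alone, with nr5a2 at least 825-fold and barhl2 at -2.95 ± 0.37. The camera call (adjusted p = 0.0298) was lost at adjusted p = 0.173 with an estimated correlation. In the 8-library fit 1 of 34 tested was higher and 5 were lower, and the call of isl1l ended (adjusted p = 0.0886). Telencephalic markers had 7 of 13 lower (9 over the list alone), tbr1a at least 68.3-fold, and the camera call (adjusted p = 0.00646) was lost at adjusted p = 0.057 with an estimated correlation. Midbrain and hindbrain markers had 8 of 19 lower and ca8, chosen after its value was seen, higher (10 and 1 over the list alone), and that camera call (adjusted p = 0.00363) was lost at adjusted p = 0.173 with an estimated correlation. All 7 erythrocyte genes tested were lower on either adjustment, slc4a1a with 2 counts against 24230 (camera adjusted p = 4.56e-06, and adjusted p = 0.00549 with an estimated correlation). Of 20 immediate early genes 5 were higher and 3 lower on either adjustment, btg2 at 1.36 ± 0.19 and egr4 at -1.54 ± 0.20; with cH libraries 1 and 2 set aside 4 were higher and 7 lower, and the median log2 fold change turned from 0.676 to -0.768. Of 17 heat shock and stress genes 4 were higher and 2 lower, gadd45ba at 1.79 ± 0.21 and ddit3 at -1.33 ± 0.19, with a median of 0.755 that went to 0.0524 without those 2 libraries. Of 76 ribosomal protein genes 13 were lower on either adjustment, rpl3 by 1.14 and rplp0 at -1.82 ± 0.23. The camera calls of those 3 lists were lost, at adjusted p = 0.692, 0.23 and 0.724 with an estimated correlation. No camera call was made for microglia (3 lower of 14), endothelial (3 lower of 16), lymphoid (1 lower of 4), meningeal (1 higher and 2 lower of 8), photoreceptor (5 lower of 14), oligodendrocyte (0 of 14), pituitary (0 of 2) or mitochondrial genes (0 of 2). Over the list alone 4 endothelial, 2 lymphoid, 3 meningeal and 1 pituitary gene were lower, and the other counts stayed as given. With cH libraries 1 and 2 set aside 0 of 19 photoreceptor and 0 of 6 lymphoid genes passed, while 2 oligodendrocyte genes and 1 mitochondrial gene were lower, as were 3 glutamatergic and 5 GABAergic genes.

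With only the 8 cH and non-cH libraries in the fit, 2157 genes passed, 885 of them higher, and 2111 were among the 4416. Lists had fewer calls there too. Lower were 8 of 29 feeding neuropeptide, 3 of 10 telencephalic, 12 of 19 pan-neuronal and 7 of 74 ribosomal protein genes, with 0 higher in each. Of 18 midbrain and hindbrain markers 4 were lower and 1 higher, and of 18 radial glia genes 10 were higher and 1 lower. The calls of isl1l, tagln2_1, gad1b, pvalb7_1 and fosab (adjusted p = 0.0127 in the 16-library fit) ended there, at adjusted p from 0.0658 (pvalb7_1) to 0.13 (fosab). Leaving out single libraries ended the calls of tgm1l3, isl1l, tagln2_1, asmt and rlbp1a. In that order they had highest adjusted p of 0.0597 (without non-cH replicate 4), 0.0629 (without non-cH replicate 4), 0.0749 (without non-cH replicate 3), 0.0722 (without non-cH replicate 2) and 0.0528 (without non-cH replicate 1). Left-out libraries also moved sizes: without cH replicate 2 the log2 fold changes of tph1a and th2 were 4.6 and 4.05, without non-cH replicate 1 that of th2 was 6.26, and without non-cH replicate 4 those of myo18aa and foxj1a were 7.46 and 5.65. The fitted change of gad1b went to -12.64 without cH replicate 4, which held most of its counts, and the bound of tbr1a to at least 39.3-fold without non-cH replicate 3. With cH libraries 1 and 2 set aside 6173 genes passed.

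The direct comparison of LH with cH cells, in which line, reporter and sort change together with the population, gave 3217 genes higher in LH and 1976 higher in cH, with 2576 in the fit of 8 libraries. Of the genes named for the largest differences, slc1a6, a neuronal glutamate transporter gene, gria3a, an AMPA receptor gene, pde11a, camk2n1b, opn8b and gfra2b were at 52.6 to 74.5 CPM in LH and at 0 in all cH libraries, at least 2320-fold (gfra2b) to 3280-fold (slc1a6) higher. Of these, opn8b also differed between the negative cells, at 3.8 ± 2.98 CPM in non-LH and 0.0129 ± 0.0257 in non-cH (adjusted p = 0.0216). Its difference between the enrichments did not pass (adjusted p = 0.0677). slc17a6a had 51716 counts in LH and 2 in cH, a ratio of 26100 (95% counting interval 7230 to 216000), and bnc2 was at 1230 ± 114 and 0.0632 ± 0.086 CPM. isl1l, isl1l_1, mecom and efcab6 were at 0 in LH and at least 2350-fold, 1220-fold, 1110-fold and 926-fold higher in cH; the last 3 bounds fell to 575-fold (without cH replicate 2), 656-fold (without cH replicate 3) and 585-fold (without cH replicate 1). Of 19 pan-neuronal markers 17 were higher in LH (camera adjusted p = 8.88e-14, and adjusted p = 0.0135 with an estimated correlation). Of 18 radial glia genes 14 were higher in cH and 1 in LH (camera adjusted p = 1.83e-17, and adjusted p = 0.00526 with an estimated correlation). Serotonergic genes were higher in cH, 6 of 15 and 7 over the list alone (camera adjusted p = 0.00176, and adjusted p = 0.0365 with an estimated correlation). Of 38 feeding neuropeptide genes 11 were higher in LH and 1 in cH (camera adjusted p = 0.00176, lost at adjusted p = 0.074 with an estimated correlation). The glutamatergic list was higher in LH with slc17a6a as its 1 call (camera adjusted p = 0.00116, and adjusted p = 0.018 with an estimated correlation). Calls for microglia (higher in LH), ependymal and heat shock genes (both higher in cH) were lost, at adjusted p = 0.543, 0.306 and 0.414 with an estimated correlation.

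The negative cells of both lines were compared to see how far the lines differ apart from the sorted population. Of 22318 genes 12 were higher in non-LH and 18 in non-cH, and 25 of the 30 were rows that share a symbol with another row. The row csdc2a_1 was at 0.155 ± 0.133 CPM in non-LH and 47 ± 18.1 in non-cH (log2 fold change -8.20 ± 1.34, adjusted p = 0.0205). tmem170a was also lower in non-LH, at -8.68 ± 1.12. adnpb_1, epb41l5_1 and emc1_1 were higher in non-LH, at 7.52 ± 0.96, 7.51 ± 1.18 and 6.78 ± 1.01. With the rows of each symbol summed, an alternative added after the data were seen, 2 genes passed, hmgb1a and LOC567978, both higher in non-LH, and 0 of the 25 symbols did; 3 of the 5 calls without copies were lost as well. In the fit of 8 libraries 138 rows passed. Of the 25 lists only ribosomal protein genes gave a camera call, higher in non-LH (adjusted p = 4.6e-25), lost at adjusted p = 0.47 with an estimated correlation. Without any single non-LH library 14 to 18 genes passed, without any single non-cH library 15 to 17, without cH replicate 1 49 and without cH replicate 2 64. Single libraries left out also ended the calls of epb41l5_1, emc1_1 and csdc2a_1, with highest adjusted p of 0.0828 (without non-cH replicate 1), 0.064 (without non-cH replicate 2) and 0.144 (without non-LH replicate 2).

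**Figure D5:**
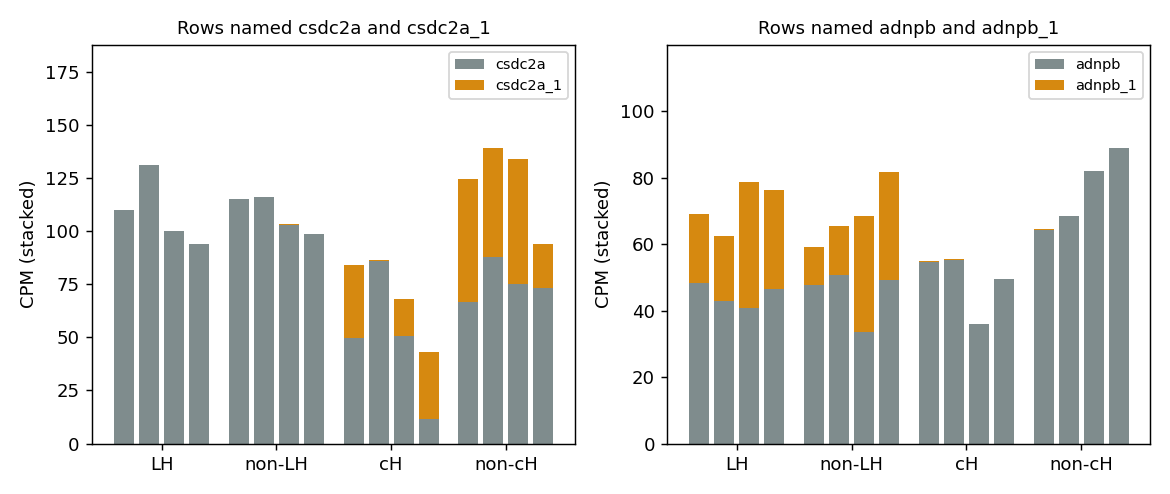
Stacked CPM of 2 rows that share a symbol, for csdc2a (left) and adnpb (right), 1 bar per library, 4 per group. The row csdc2a_1 takes counts in both fractions of the cH line, apart from cH replicate 2 at 0.354 CPM, and adnpb_1 takes counts in both fractions of the LH line.

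The difference between the 2 enrichments, (LH against non-LH) minus (cH against non-cH), which removes line differences shared by positive and negative cells, passed for 2629 genes, 1688 of them positive. kita, a receptor tyrosine kinase gene, was at 47.9 ± 10.8 CPM in LH and 0.689 ± 0.80 in non-LH, and pnck, a calmodulin-dependent kinase gene, at 40.6 ± 9.25 and 0.589 ± 0.666, with adjusted p of 0.00365 and 0.0267 for the difference. cfi, the complement factor I gene, was at 4.44 ± 2.50 and 0.127 ± 0.253 CPM (adjusted p = 0.00309). All 3 were at 0 in cH, against 3.53 ± 2.57 (kita), 1.42 ± 2.85 (pnck) and 11.4 ± 9.27 CPM (cfi) in non-cH, so their differences hold that absence too. On the negative side were efcab6, gal3st1b and kif13bb (adjusted p = 0.00319, 0.0277 and 0.00739). Their fitted sizes rest on groups at or near 0, so only their sign is read. The calls of pnck and gal3st1b ended without non-cH replicate 1 and without non-LH replicate 1, each at adjusted p = 1.

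Genes that changed the same way in both enrichments exceeded the number that independent lists would share. Of the 138 genes higher in LH and the 1542 higher in cH, 44 were in both, against 9.53 by chance. Of the 197 and 2874 lower genes 88 were in both, against 25.4. Opposite calls also exceeded chance: 32 genes were higher in LH and lower in cH (17.8 by chance), and 34 the reverse (13.6). Both contrasts use 1 estimate of the spread per gene, so the lists are not independent. The excess alone therefore does not show shared change. The 132 genes called the same way became 275 in the 8-library fits and 472 with cH libraries 1 and 2 set aside, both chosen after the data were seen, and were fewer with a block on the sample number. Across all 22318 genes the log2 fold changes had r = 0.111 and rho = 0.0247, and genes are not independent replicates. hbaa1 and ba1 were lower in both enrichments, and th2 was lower in LH and higher in cH.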

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

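All tests of the first pattern (copy rows) and of the last (heat shock), and those of lost transcripts and of carried-over glial cells in the second, were chosen after the result or values close to it were seen. All 5 counts of genes exceeded those of other splits: with group labels exchanged among the 8 libraries compared, 1 of 35 splits, the real one, reached the count, with 335 genes against at most 1 in another split for LH against non-LH, 4416 against 39 for cH against non-cH, 5193 against 8 for LH against cH and 30 against 1 for non-LH against non-cH. For the difference of the 2 enrichments, with the positive and negative library of a number exchanged together between lines, it was 2629 against 1. A share of 1 in 35 is the smallest that these splits can give. The other splits mix the compared groups, which adds their difference to the spread and lowers the counts. The real split ranked first, but the splits cannot exclude chance.

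A first pattern is that 25 of the 30 genes called between the negative cells are rows that share a symbol. Such rows are 24.2% of the genes tested, so their share among the calls is not chance (one-sided Fisher's exact p = 1.4e-11). Sorting of the negative cells is argued against, since 24 of the 25 rows were called in the same direction between LH and cH cells, where the line is what the 2 comparisons share. A line variant that decides which of 2 near-identical copies takes the reads is a candidate explanation: with rows summed, the median size of the log2 change went from 6.32 to 0.22 and 0 of the 25 symbols stayed called, though 3 of the 5 other calls were lost too at unchanged sizes; why was not tested, and the count alone therefore decides little. The explanation is argued against for the 3 symbols that kept at least 0.5 of their change, over 2 SE from 0: zgc:158343 (-2.47 before and after), etv5b (-1.69 to -1.03) and tfr1b (2.09 to 1.12); no biological explanation was tested.

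The second pattern is the glial content of cH cells. Loss of transcripts in cH libraries 1 and 2, which detected the fewest genes, is argued against as its whole cause. The median log2 fold change of the radial glia list was 2.38 with all libraries and 2.49 with those 2 set aside. The pan-neuronal median was then -4.60 against -3.32. However, cH libraries 3 and 4 also detected fewer genes (18588 and 18779) than any library of the other groups (at least 20997). Loss common to all 4 cH libraries was therefore not tested. For a few genes taking most counts, the median of the radial glia list was 2.52 once the 100 most abundant cH genes were left out of the library sizes. Leaving them out shifts all genes of a library alike and could hardly lower the median, so this test does not decide. Glial cells carried into the positive gate cannot be told apart from glia that the driver labels, as both enter through the same sort. The quartiles of the markers' log2 changes lay 3.11 apart (0.48 to 3.6), past the bound of 2 that was to exclude carried-over cells. Dividing-cell genes such as mki67 are not the only low ones: her4.2 (0.67), notch1b (0.59), sox9b (0.45) and nes (-0.18) also changed little. The spread argues against carried-over cells that raise all listed markers together. Carry-over of other kinds was read as open only after the spread was seen. Cells taken at random from the negative fraction could not raise slc1a2b above its non-cH level, and labelling of astroglia by the driver stays open as an untested biological explanation.

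Another pattern is that heat shock genes of the cH line took 1.25% and 1.34% of counts in cH samples 1 and 2 against 0.448% and 0.495% in samples 3 and 4, and 1.18% and 0.877% against 0.262% and 0.241% in non-cH; hsp70l averaged 4380 against 154 CPM in cH and 3690 against 44.8 in non-cH, with smaller differences the same way in LH (1410 against 696) and non-LH (731 against 448). Library size is argued against, since the totals of samples 1 and 2 were 0.796 times those of samples 3 and 4 in cH and 1.1 times in non-cH. A processing batch shared by samples 1 and 2 cannot be told apart from other causes: across genes the same difference correlated by only 0.0531 between cH and non-cH, against 0.0154 and 0.0147 for the other ways to pair the numbers. The spread among cH libraries, with a median correlation of 0.654, lowers any such value, so a low one does not exclude a batch that moved few genes, and the labels give none. That value missed the bound of 0.1, and was read as open only after it was seen.

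Single libraries set apart from the other 3 of their group were found in 18 of 256 groups tested, where chance flags about 5%. Many of them can therefore be chance, and a flag can mark a small gap. For example, egr4 in non-cH was at 1000 CPM in replicate 1 and at 840 to 867 CPM in the others. The number given is the gap to the nearest library over the whole range. Among genes these were kif13bb (0.959), slc6a1b (0.867), rfx2 (0.864), tac1 (0.912) and isl1l_1 (0.904) in cH, slc1a6 (0.878) in LH, and eomesb (0.916), gad1b (0.962) and egr4 (0.835) in non-cH. Among shares of counts they were the 10 most abundant genes (0.843), meningeal genes (0.916), photoreceptor genes (0.933) and mitochondrial transcripts (0.882) in non-cH, hypothalamic transcription factors (0.907) and lymphoid genes (1, with counts in 1 library only) in cH, telencephalic (0.868) and midbrain and hindbrain markers (0.838) in LH, and mitochondrial transcripts (0.854) in non-LH.

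The enrichment in LH differed from that in cH for 54 of the 98 genes named in either comparison, by the edgeR test of the difference at an adjusted p under the threshold. The log2 differences, LH minus cH, were positive for add3b (3.89), kctd4_1 (5.16), prkcbb (3.94), nrgna (6.30), onecutl (13.31), slc6a1a (1.49), egr4 (2.60), egr3 (2.32), gad1b (7.03), npy (8.36), barhl2 (2.19), en2a_1 (6.52), pvalb7_1 (9.19), elavl4 (2.56), stmn2a (4.76), ddit3 (1.74) and rpl3 (0.70), and for ba1 (4.33) and hbaa1 (4.84), which were lower in both. They were negative for th2 (-10.85), slc6a1b (-3.36), foxb1a (-1.95), zic1 (-1.63), pcna (-1.36), her4.2 (-2.51), dcn (-3.67), tph1a (-5.69), myo18aa (-4.61), mao (-2.70), gch1 (-4.21), id1 (-3.67), sox2 (-2.83), rfx2 (-2.00), foxj1a (-5.04), btg2 (-1.02) and gadd45ba (-1.49). For genes with 0 to 3 counts in a group the fitted difference depends on the fit's prior count and only its sign is read: epb41b (9.13), slc17a6a (14.23), scrt1a (13.73), eomesb (12.15), golga7bb (13.21), mrc1a (11.31), uts1 (11.90), tacr3l (9.60), npy8ar (11.65), drd3 (10.29), nr5a2 (12.29), tbr1a (7.74), slc4a1a (8.82), fezf2 (-8.76), kif13bb (-16.66), lrguk (-12.62), efcab6 (-18.28) and isl1l (-13.28).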

How the results depend on the processing

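Counts of genes changed with the libraries in the fit, the tool and the block. The alternatives that set cH libraries aside or sum rows, and the overlap in the 8-library fits, were chosen after the data were seen, the others before. With only the 8 libraries compared, LH against non-LH gave 2548 genes in place of 335, cH against non-cH 2157 in place of 4416, LH against cH 2576 in place of 5193 and non-LH against non-cH 138 in place of 30. For the comparisons with cH, fewer libraries and the spread of cH cannot be separated, and the cause was not tested. With cH libraries 1 and 2 set aside LH against non-LH gave 1396, non-LH against non-cH 122 and the difference of enrichments 4977 in place of 2629. With all 4 set aside the first 2 gave 2356 and 177. Both counts thus rose without cH libraries in the shared estimate of the spread. The cH libraries varied more: they correlated by 0.614 to 0.79 with each other, against 0.855 to 0.884 within LH and 0.884 to 0.895 within non-LH. The spread per gene was not compared. DESeq2 gave 1356, 6702, 441 and 4641 genes for LH against non-LH, cH against non-cH, the negative cells and the difference. It made mostly false calls in simulated data, where all groups had the same spread per gene, unlike the real groups. limma-voom gave 3348 for LH against non-LH and 432 for the negative cells; the cause was not tested. Summed rows gave 2 for the negative cells, with 3 of the 5 calls without copies lost as well; why was not tested. Of the LH against non-LH calls 41.2% were higher, against 54.1% with the 8 libraries and 60% with the replicate block; of the calls between negative cells 40%, against 53.7% with DESeq2, 25% with the block and 100% with summed rows.

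Genes called the same way in both enrichments numbered 132, against 275 with the 8-library fits and 472 with cH libraries 1 and 2 set aside.

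Each library left out in turn gave 141 to 599 genes for LH against non-LH, 3577 to 5252 for cH against non-cH, 4173 to 6132 for LH against cH, 14 to 64 for the negative cells and 1995 to 3602 for the difference. The LH range has libraries of that line at its low end, where fewer samples are compared, and cH libraries at its high end.

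No label says that the numbers pair samples. Same-numbered libraries deviated together by at most 0.0462 (cH and non-cH) and 0.0436 (LH and non-LH), none of the pairs over 0.1. All 4 cH libraries still correlated best with the non-cH library of their own number. Single genes could also move with the number, as did hmox1a, chosen after its values were seen. It was at 156 CPM in LH replicate 3 and 67.6 in non-LH replicate 3. The other LH libraries were at most at 17.1 and the other non-LH libraries at most at 13.1. These values do not settle whether the numbers pair samples. If the numbers do, the results with the block are the ones to read. With a replicate block LH against non-LH gave 80 genes, 77 of them among the 335, the negative cells 12, the difference 1597, and genes shared by both enrichments 31; the other counts stayed within 1.5 times. Under the block tac1 in cH turned to -1.71, and the tests of the glutamatergic list in LH (adjusted p = 0.636) and the GABAergic (0.977) and growth hormone lists (0.929) in cH changed direction without a call on either side. In LH the photoreceptor (adjusted p = 0.0149, lower) and heat shock lists (0.0156, higher) gained a call. These tests used the preset correlation, and with the block no estimated correlation was tried.

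Of 140 results for named genes, 140 kept their call and direction with RLE scaling, 139 with upper-quartile scaling and 138 without a filter. The number was 110 with limma-voom and 107 with the block, where 32 were weaker and 1 was reversed. Other directions that turned were those of tac1 in cH with limma-voom (-1.78), without cH replicate 2 (-2.03) and with cH libraries 1 and 2 set aside (-1.47), of adnpb_1 (-0.15), epb41l5_1 (-0.41) and emc1_1 (-0.07) with rows summed, and of 4 uncalled genes when 1 library was left out: in LH tph1a (0.06 without LH replicate 1 and 0.07 without non-LH replicate 2; range -0.67 to 0.07), slc6a4b (0.57 without non-LH replicate 2; -7.88 to 0.57) and hcrt (-0.32 and -0.41 without LH replicates 1 and 4, -0.20 without non-LH replicate 1, 2 or 3; -0.41 to 6.45), and in cH slc17a8 (0 without non-cH replicate 4; -7.09 to 0). Over all libraries left out tac1 in cH ran from -2.03 to 1.16. The cause was not tested. Depth limits low genes: 3 counts over a group correspond to 0.0172 to 0.0227 CPM.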

Other observations

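Some biology that the comparisons leave aside concerns markers with wide ranges within a group. Oligodendrocyte genes took 1.25% and 1.64% of counts in LH samples 1 and 2 but 0.301% and 0.192% in samples 3 and 4, against 1.40% ± 0.201 in non-LH (SD, n = 4). Microglia genes took 0.363% ± 0.165 in LH, 0.188% ± 0.0333 in non-LH and 0.0626% ± 0.0405 in cH. In cH, tph1a was at 230 and 401 CPM in samples 1 and 2 and at 27.7 and 28.6 in samples 3 and 4. The values of single samples were not compared by a test.

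The following 3 genes of dopamine signalling and monoamine transport were named after their values were seen. The dopamine transporter gene slc6a3 was higher in cH than in LH (log2 fold change of LH against cH -3.68 ± 0.90), as was the D2 receptor gene drd2b (-2.54 ± 0.71), which was also higher in cH than in non-cH (2.67 ± 0.71). The vesicular monoamine transporter row slc18a2_1 was higher in cH than in LH (-5.79 ± 1.74). Rows with such endings can differ between the lines, and neither another row of this symbol nor a sum is given here. No change against non-cH is given for slc6a3 or slc18a2_1, so a line difference cannot be told apart from one of the population. The catecholaminergic list had no camera call in LH against cH (adjusted p = 0.22).

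Between the negative cells, 5 calls were not copy rows. Higher in non-LH were hmgb1a (3.6 ± 0.43), opn8b (669 counts in non-LH and 2 in non-cH) and 2 genes with provisional names. itm2ca (-2.11 ± 0.37) was lower. With rows summed the calls of opn8b (adjusted p = 0.11) and itm2ca (0.168) were lost.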
